A study of Mus musculus with 2 samples.

How the data were processed

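Polyadenylated RNA was measured by sequencing in 2 technical libraries of the sigmoid colon of 1 female C57BL/6J mouse, extracted per the labels with a kit for lipid-rich tissue. Both libraries are of 1 biological replicate and form 1 group, so no groups were compared and no p-value covers variation between mice. The libraries are named by the technical replicate number in the labels.

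The authors deposited, for each library, a table of genes and a table of transcripts on mouse assembly mm10 with the GENCODE M4 annotation, per the text files beside them. The aligner, the quantifier, its version and its strand setting are not given in the sources used here, so reads of a gene and of an antisense partner may have been counted together. The setting may also differ between the libraries, so a difference between them in a gene that overlaps an antisense gene may come from it. Per the file headers, the tables hold the authors' expected counts, which are estimated counts in which reads matching several transcripts were shared out by a model. The value had a decimal part above 0 as written in the file for 3.62% of the Ensembl genes in library 1 and 5.42% in library 2. The authors' TPM values, corrected for length and summing to the same total over each file, the authors' FPKM values, and a posterior mean of the TPM stand beside them, per the file headers. The deposited transcript tables also give each transcript's share of its gene in percent, per the file headers. Each file lists 69691 entries, of which 43346 are Ensembl genes, 97 are spike-in entries that had 0 counts in both libraries, and 26248 carry numeric identifiers with 0 counts in library 1 and 1 in library 2. Only the Ensembl genes were used.

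Symbols came from a table of gene names that matched 42462 of the 43346 genes; the other 884 kept their identifiers. Positions, gene types and transcript sequences came from GENCODE M21 on GRCm38, which is the same assembly as mm10 with a later annotation. Of 103639 transcripts, 97.9% had a sequence there and 88.2% had the same length. A gene's GC content is the mean over its transcripts weighted by their TPM in both libraries. Of the genes tested, 99.7% had a value. A nuclear gene was taken as a copy of a mitochondrial gene when at least 50% of its 31-base words occurred in that gene, which found 7.

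Depth was 25843064 expected counts in library 1 and 20681575 in library 2, of which the 10 most abundant genes took 29.96 and 9.64%. Shares of counts have 95% Wilson intervals. A count of 0 was read against a floor of 3 counts per library.

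Levels are TPM per library with the mean and SD over both. The following were fixed before the data were examined: 46 gene lists, 15 genes for transcript shares, the tests and the alternatives planned. The lists comprise 20 cell types (epithelium, colonocyte, goblet, enteroendocrine, tuft, stem, smooth muscle, interstitial cell of Cajal, enteric neuron, enteric glia, fibroblast, blood and lymphatic endothelium, mesothelium, adipocyte, B and plasma, T, macrophage, mast and red blood cells) and 8 other tissues. The rest are the 4 Hox clusters, intestinal transcription factors, niche Wnt signals, BMP and hedgehog signals, antimicrobial defence, proliferation, immediate early genes, electron transport, ribosomal proteins, mitochondrially encoded proteins, histones, very long transcripts, nuclear long non-coding RNAs, X inactivation and Y-linked genes. The genes named were the 20 nuclear genes with the highest mean TPM, up to 5 members of each list with the highest mean TPM, members below 0.1 TPM in both libraries, any Hox gene, the 10 highest and 10 lowest ratios among genes that passed with a mean count of at least 100, and the transcript-share genes with a mean of at least 5 TPM. Any other named gene is marked as chosen after its values were seen or is given only as part of a sum with near-identical genes. Some genes that this rule takes are not reported here.

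Expected counts were rounded to whole numbers for tests. A gene entered with a mean expected count of at least 10. With 1 library on each side there are no residual degrees of freedom for edgeR's quasi-likelihood test. The main test was therefore a two-sided exact binomial test of each gene's counts given the effective library sizes (TMM, edgeR 4.0.16 in R 4.3.3; library 2 over library 1 was 1.35), adjusted by Benjamini-Hochberg. A gene passed at an adjusted p under 0.05 and at least 2-fold. Ratios used a prior count of 0.5, and an SE beside a ratio covers counting only. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, as a description of these libraries. Trends were fitted by lowess with a fraction of 0.2 (statsmodels 0.14.6 in Python 3.11.15, with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6) and taken off the expected ratio. Agreement was described by correlations, by chi-square and by edgeR's common dispersion over the libraries, whose square root was 94.8%. Figures were drawn with matplotlib 3.10.9.

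The tests were tried on counts simulated for 15664 of these genes with 200 genes changed. The simulated counts held counting noise only, with a straight-line GC trend where one was added. The real libraries varied by more than counting noise, so the false calls below do not measure error among the real calls. Without a GC trend, 92% of genes changed 2.5-fold, 88% of those changed 4-fold and 96% of those changed 8-fold were recovered, with 1 false call. With a GC trend taken off the values were 94, 86 and 96%, with 2 false calls. Genes changed 1.5-fold were recovered in 0 and 2% of cases, as the 2-fold rule implies. Of simulated lists with no shift, drawn from independent normal values without GC or expression structure, 93% fell between percentiles 5 and 95.

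The alternatives chosen at that time were DESeq2 1.42.0 size factors, total counts, upper quartile scaling, other count minimums, a 1.5-fold limit, edgeR's exact test with the common dispersion, a length trend, a length and GC trend together, FPKM, posterior mean and protein-coding TPM, list medians, TPM ratios, other TPM thresholds, and each library alone. Leaving out mitochondrial genes, the GC trend alone, genes of 46 to 52% GC, random lists matched on GC and other definitions of GC content were added after seeing the data.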

Results

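Polyadenylated RNA of the sigmoid colon, the last bend of the large intestine before the rectum, was sequenced from 1 adult female mouse of the C57BL/6J inbred strain, 10 weeks old. The labels give 2 technical libraries of this 1 mouse, here called library 1 and library 2 after their technical replicate numbers. Library 2 was made in 2015, after library 1 had been published. There was 1 group and no second condition or animal. Each ± beside a TPM or a transcript share is therefore an SD over n = 2 technical libraries. It covers whatever differed between these libraries, such as library preparation and sequencing, but not differences between mice. Library 1 held 25843064 expected counts and library 2 held 20681575. Mitochondrial genes and their nuclear copies took 33.9% of the counts of library 1 (95% Wilson interval 33.8 to 33.9%) and 8.42% of those of library 2 (8.41 to 8.44%). A count of 0 allowed up to 3 counts, or 0.116 CPM (counts scaled to library size) in library 1 and 0.145 CPM in library 2. Intervals and floors cover counting error only, since the sources used here name no molecular identifiers. Mitochondrial genes and their copies took 67.3% of the TPM of library 1 and 21.8% of that of library 2. A close pair of TPM values can therefore go with a difference in scaled counts. Likewise, a TPM sum that is higher in library 2 can be lower there over nuclear protein-coding genes alone. The labels state no question beyond profiling this tissue, so the levels of gene groups are given first and the 2 libraries are compared afterwards.

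Genes of mucus-secreting goblet cells had the highest summed level of the 20 cell type lists. Their 11 genes summed to 4807 TPM (length-corrected transcript abundance) in library 1 and 30848 TPM in library 2 (17828 ± 18414, SD, n = 2). Zg16, a lectin-like protein of the mucus layer (ENSMUSG00000049350.5, chromosome 7, 127050156 to 127087328, GRCm38), was at 472 and 10145 TPM. Muc2, the gel-forming mucin of the gut (ENSMUSG00000025515.11, chromosome 7, 141690340 to 141754693), was at 2106 and 6464 TPM. Clca1, a secreted mucus-processing protease, was at 1299 and 4031 TPM, and Agr2, a disulfide isomerase of the mucin-making endoplasmic reticulum, was at 727 and 2268 TPM.

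The 14 genes of absorptive colonocytes summed to 4179 and 17101 TPM (10640 ± 9137). Lypd8, a surface protein that keeps flagellated bacteria off the epithelium (ENSMUSG00000013643.9, chromosome 11, 58379043 to 58390728), was at 1788 and 9734 TPM. Car1, a carbonic anhydrase, was at 1085 and 1459 TPM (1272 ± 264), and Slc26a3, the chloride and bicarbonate exchanger, was at 667 and 587 TPM (627 ± 56.7). The general epithelial list of 12 genes summed to 1262 and 13587 TPM (7425 ± 8715). Within it Epcam, a cell adhesion molecule of all gut epithelium, was at 451 and 955 TPM, and Krt8, a simple-epithelium keratin, was at 60.7 and 2931 TPM.

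Rarer epithelial cells were measured at lower levels. The 9 enteroendocrine genes summed to 157 and 737 TPM (447 ± 410). Gcg, which encodes proglucagon and the L-cell hormone GLP-1, had the closest TPM pair of its 5 most abundant members at 87.9 and 95.3 TPM (91.6 ± 5.28). By scaled counts Gcg passed as lower in library 2 (log2 ratio -1.11), and another of the 5, Chgb, had a smaller change (1.01). Insl5, a peptide of distal colon L cells, was at 35.8 and 266 TPM, and Pyy, an appetite hormone of the same cells, was at 2.95 and 219 TPM. The 10 stem cell genes summed to 278 and 289 TPM (283 ± 7.23), or 888 and 383 TPM over nuclear protein-coding genes alone. The stem cell list included Slc12a2, a sodium, potassium and chloride cotransporter of the crypt base, at 145 and 83.8 TPM. It also held Sox9, a transcription factor of crypt progenitors, at 20.8 and 19.97 TPM (20.4 ± 0.573). By scaled counts Sox9 passed as lower in library 2 (log2 ratio -1.23). The 10 proliferation genes summed to 155 and 203 TPM, with Pcna, the DNA polymerase clamp, at 83.6 and 72.8 TPM and Mki67, a marker of cycling cells, at 16.1 and 16.8 TPM. Both Pcna and Mki67 passed as lower in library 2 by scaled counts (log2 ratios -1.06 and -1.11). The proliferation sums were 493 and 269 TPM over nuclear protein-coding genes alone. The 8 tuft cell genes summed to 10.6 and 34.7 TPM. Among them Dclk1, a kinase that marks these chemosensory cells, was at 8.14 and 6.42 TPM, and the tuft cytokine Il25 was below 0.1 TPM in both libraries.

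Of the muscle wall, smooth muscle ranked 3 of the 20 cell type lists by summed level in library 1, above the general epithelial list, and 4 in library 2. The 15 smooth muscle genes summed to 1319 and 8085 TPM (4702 ± 4785). Tpm1, a tropomyosin, was at 545 and 1075 TPM, and the enteric smooth muscle actin Actg2 was at 84.9 and 1207 TPM. Genes of interstitial cells of Cajal, the pacemakers of gut motility, summed to 63.7 and 338 TPM over 4 genes, with the chloride channel Ano1 at 22.2 and 158 TPM and the receptor tyrosine kinase Kit at 15.4 and 33.7 TPM. The 17 enteric neuron genes summed to 110 and 162 TPM (136 ± 36.7), or 351 and 215 TPM over nuclear protein-coding genes alone. Vip, a relaxing neuropeptide, was at 54.5 and 37.5 TPM (46 ± 12.0), and Tac1, which encodes the contracting peptide substance P, was at 19.6 and 19.4 TPM (19.5 ± 0.191). The 7 glial genes summed to 73.0 and 160 TPM, and most of this was Erbb3, a neuregulin receptor that epithelium also makes, at 57.3 and 139 TPM. Their sums were 233 and 212 TPM over nuclear protein-coding genes alone.

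Among connective tissue and vessels, fibroblasts ranked 5 of the 20 cell type lists in library 1 and 6 in library 2, adipocytes 8 and 10, blood endothelium 16 and 15, and lymphatic endothelium 15 and 16. The 12 fibroblast genes summed to 759 and 1064 TPM (911 ± 216), led by the collagen Col3a1 at 260.1 and 334 TPM and the proteoglycan Dcn at 257 and 261 TPM (259 ± 2.34). By scaled counts Dcn passed as lower in library 2 (log2 ratio -1.13). The fibroblast sums were 2422 and 1412 TPM over nuclear protein-coding genes alone. The 8 blood endothelium genes summed to 23.0 and 119 TPM, with Pecam1, an endothelial junction protein, at 4.41 and 27.2 TPM. The 4 lymphatic genes summed to 24.6 and 34.8 TPM, of which Lyve1, a hyaluronan receptor, gave 17.8 and 19.1 TPM. The 7 mesothelium genes summed to 6.54 and 11.6 TPM. Over nuclear protein-coding genes alone the lymphatic list summed to 78.5 and 46.1 TPM and the mesothelium list to 20.9 and 15.4 TPM. The 10 adipocyte genes summed to 161 and 390.0 TPM, led by the carbonic anhydrase Car3 at 115 and 109 TPM (112 ± 4.74), and Adipoq, the adipocyte hormone adiponectin, was at 9.30 and 26.8 TPM.

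Among immune cells, the 9 B and plasma cell genes were led by Jchain, the joining chain of secreted IgA, at 405 and 391 TPM (398 ± 9.89), and the list summed to 446 and 484 TPM (465 ± 26.9). Over nuclear protein-coding genes alone this list summed to 1423 and 642 TPM. The 11 macrophage genes summed to 129.9 and 682 TPM, with Lyz2, lysozyme, at 94.6 and 397 TPM and the complement gene C1qa at 1.56 and 66.9 TPM. Lyz2 shares sequence with Lyz1, so their split is uncertain. Together they had 103 and 414 TPM. The 10 T cell genes summed to 5.13 and 27.5 TPM and the 6 mast cell genes to 4.42 and 7.78 TPM. The mast cell sums were 14.1 and 10.3 TPM over nuclear protein-coding genes alone. The 5 red blood cell genes summed to 70.9 and 2803 TPM.

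**Figure D1:**
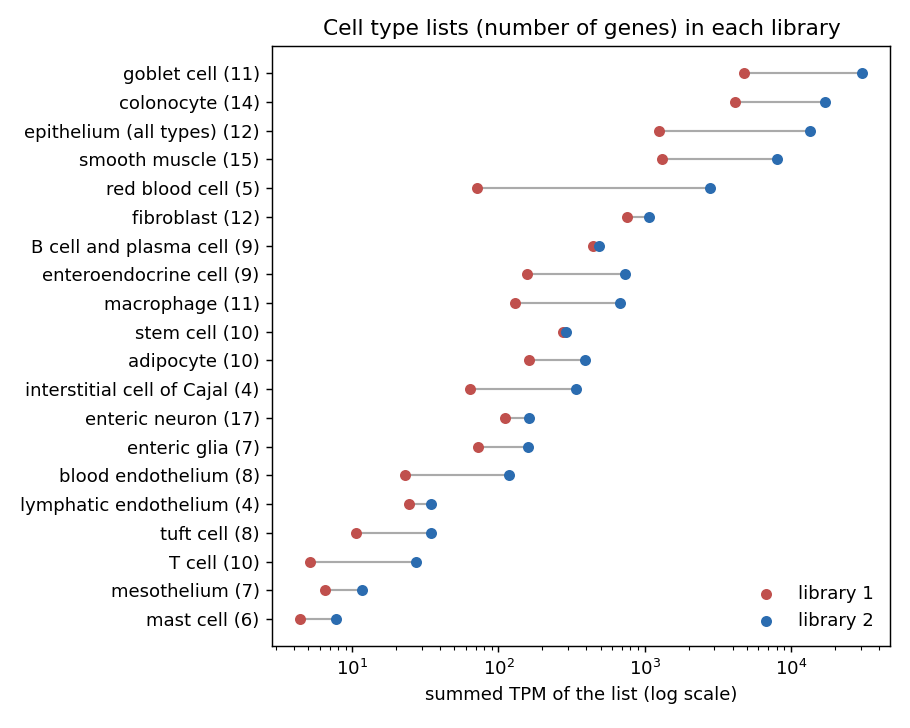
Summed TPM (horizontal axis, log scale) of the 20 cell type lists, 1 line per list with its number of genes, in library 1 (red) and library 2 (blue). Goblet cell, colonocyte and general epithelial lists have the highest values in library 2, and the B and plasma cell and stem cell lists have the closest pairs of these sums. Over nuclear protein-coding genes alone, those lists lie further apart, at 1423 and 642 TPM and at 888 and 383 TPM. The fibroblast list, higher in library 2 here, is lower there on that scale (2422 and 1412 TPM).

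Markers of neighbouring organs and other cell types were measured as well. Of the 8 small intestine genes, which summed to 5.14 and 84.3 TPM, Rbp2, a retinol-binding protein of absorptive cells, made up 4 and 71.0 TPM, while the lactase gene Lct was below 0.1 TPM in both. The 6 Paneth cell genes summed to 8.28 and 18.5 TPM and were mostly Lyz1, at 7.96 and 16.2 TPM, with the defensins Defa17 and Defa30 listed at 0. The 7 stomach genes summed to 0 and 1.79 TPM, and the 8 squamous epithelium genes to 0.06 and 1.29 TPM. The 8 pancreas acinar genes summed to 14.9 and 109.7 TPM, with the elastase Cela2a at 1.68 and 37.0 TPM and the lipase Pnlip at 7.21 and 15.2 TPM. The 8 skeletal muscle genes summed to 0.68 and 34.0 TPM, from the muscle creatine kinase Ckm and the skeletal actin Acta1. In the 4-gene urothelium list, Foxa1, a transcription factor that gut epithelium also makes, was at 43.7 and 38.4 TPM, and the uroplakin Upk3a was below 0.1 TPM in both. The 6 female reproductive tract genes summed to 5.59 and 15.2 TPM.

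The homeobox genes that mark position along the body axis were read as a second check of the tissue. The most posterior members of clusters A, B and D were among the most abundant Hox genes. Hoxa13 was at 52.5 and 33.9 TPM (43.2 ± 13.2), Hoxd13 at 40.8 and 25.8 TPM (33.3 ± 10.6), and Hoxb13 at 12.8 and 172 TPM (92.5 ± 113). Cluster A summed to 159 and 231 TPM over 11 genes, with Hoxa9 at 35.9 and 50.4 TPM and Hoxa10 at 29.6 and 39.1 TPM. Its sums were 507 and 306 TPM over nuclear protein-coding genes alone. Cluster B summed to 48.8 and 226 TPM over 10 genes, with Hoxb9 at 30.1 and 39.3 TPM. Cluster D summed to 51.7 and 40.1 TPM over 9 genes, with Hoxd10 and Hoxd11 both near 4.1 TPM in each library. The whole of cluster C summed to 0.50 and 0.90 TPM over 9 genes, and its highest gene, Hoxc4, was at 0.35 and 0.31 TPM (0.33 ± 0.0283).

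**Figure D2:**
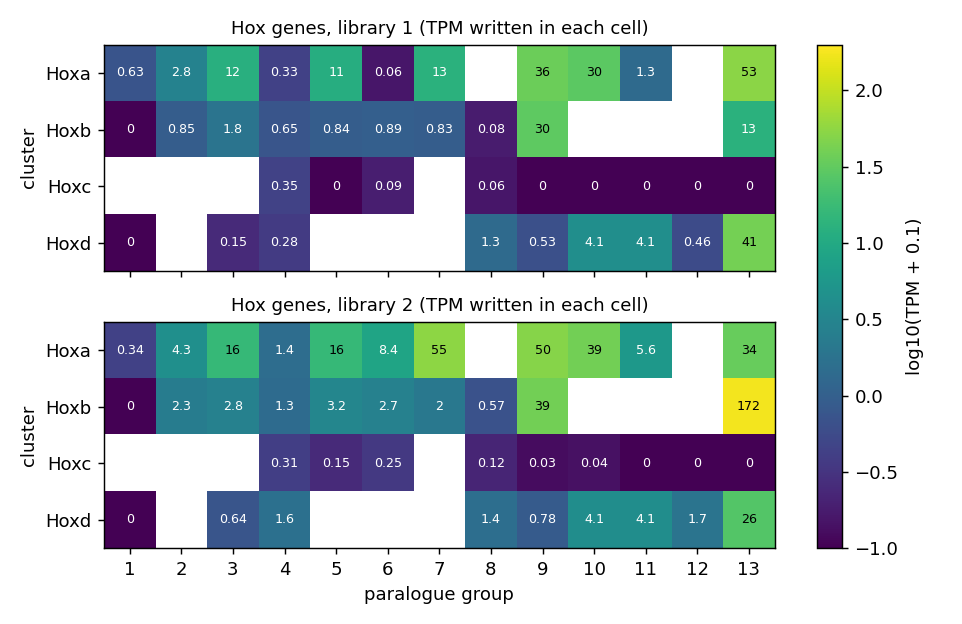
TPM of each Hox gene in library 1 (top) and library 2 (bottom), by cluster (vertical axis) and paralogue group (horizontal axis), with colour on a log10 scale of TPM + 0.1 and blank cells where no gene is listed. Hoxa13, Hoxb13 and Hoxd13 lie at 12.8 TPM or more in both libraries, and no cluster C gene is above 0.35 TPM.

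The 12 intestinal transcription factors summed to 409 and 1622 TPM. Klf4, a factor of goblet cell differentiation, was at 214 and 312 TPM (263 ± 69.0), Hnf4a, a nuclear receptor of gut epithelium, at 49.2 and 348 TPM, and Cdx1, a caudal-type homeobox factor, at 2.18 and 198 TPM. Gata4, a factor of the proximal small intestine, was at 0.10 and 0.16 TPM (chosen after its values were seen). The labels give a female mouse. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254), was at 331 and 210 TPM (271 ± 85.3), its antisense gene Tsix was below 0.1 TPM in both, and the 4 Y-linked genes summed to 0.01 and 0 TPM.

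The 2 libraries were then compared with each other, which asked how closely technical replicates of 1 tissue matched. Most genes of the general epithelial, goblet cell, smooth muscle and red blood cell lists were higher in library 2, and all 13 mitochondrially encoded protein genes were lower. This holds before the GC trend described below was taken off. Of the 12 general epithelial genes, 9 were higher in library 2, 1 was lower (Cdh17, a cadherin of gut epithelium, chosen after its value was seen) and 2 did not pass the test, with a median log2 ratio of library 2 over library 1 of 4.32 (19.97-fold), at percentile 100 of 10000 random lists matched on expression. Krt19, a simple-epithelium keratin, had 394 counts in library 1 and 35864 in library 2 (log2 ratio 6.08 ± 0.07, where ± beside a log2 ratio is the counting SE). Of the 15 smooth muscle genes, 10 were higher, 1 was lower and 4 did not pass, with a median of 2.39 (5.26-fold, percentile 100). Here Tagln, an actin-bundling protein, had 2476 and 23970 counts (log2 ratio 2.85 ± 0.03), while Tpm1 had 18065 and 23740 counts (-0.04 ± 0.01).

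Goblet cell genes had a median log2 ratio of 2.27 (4.82-fold, percentile 99.8), with 7 of 11 higher, 0 lower and 4 not passing. Tff3, a trefoil peptide that repairs mucosa, had 36 and 15643 counts (8.32 ± 0.24), whereas Clca1 had 85910 and 159607 counts (0.46). For colonocyte genes the median was 1.23 (2.35-fold, percentile 99.1), with 8 of 14 higher, 1 lower and 5 not passing. Guca2a, which encodes the gut hormone guanylin, had 111 and 14747 counts (6.62 ± 0.14), and Slc26a3 had 40764 and 22250 counts (-1.30 ± 0.01). The 5 red blood cell genes were all higher, with a median of 4.50 (22.7-fold, percentile 99.8), the same with Hba-a1 at its floor of 3 counts in library 1. The genes Hba-a1 and Hba-a2 encode the same α-globin and their split is uncertain, so they are best read as a sum, which was 163 counts in library 1 and 9149 in library 2 (41.6-fold). The macrophage median was 2.42 (6 of 11 higher, 1 lower, percentile 97.3), or 0.94 with the GC trend described below taken off.

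Other lists also had high medians. They were 2.43 for enteric glia (4 of 7 higher, 2 lower; -0.61 at a mean expected count of at least 50), 2.29 for tuft cells (5 of 7 higher, 1 lower), 1.65 for adipocytes (5 of 9 higher, 1 lower) and 1.49 for blood endothelium (5 of 8 higher, 1 lower). For pancreas acinar genes the median was 2.46 (6 of 8 higher, 1 lower), for small intestine genes 3.06 (4 of 5 higher, 1 lower), or 2.63 with Apoa4, an apolipoprotein with 0 counts in library 1, at its floor, and for intestinal transcription factors 1.31 (6 of 11 higher, 1 lower). B and plasma cell genes had a median of 1.16 and enteroendocrine genes 1.01 (0.13 with the length trend taken off). T cell genes had 0.81 (-0.09 with the length trend taken off) and genes of interstitial cells of Cajal 0.47. Medians were below 0 for proliferation (-0.31), lymphatic endothelium (-0.59), mesothelium (-0.54), mast cells (-0.02) and the female reproductive tract (-0.83). The first 4 turned positive by the ratio of TPM values (0.80, 0.57, 0.56 and 1.03), and the last at a mean expected count of at least 50 (0.62).

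Some lists had members on both sides. Stem cell genes had a median of 0.06 with 3 of 10 higher, 3 lower and 4 not passing (percentile 55.3), and fibroblast genes 0.18 with 4 of 12 higher, 2 lower and 6 not passing (percentile 78.9; -0.16 with the length trend taken off). Among 17 enteric neuron genes 5 were higher, 3 lower and 9 did not pass (median 0.37, percentile 38.3). With the trend of the ratio with GC content (share of G and C bases, described below) taken off, an alternative chosen after seeing the data, more members were lower than higher: 0 stem cell genes were higher and 3 lower (median -0.71), 1 fibroblast gene higher and 5 lower (-0.54), and 0 neuron genes higher and 6 lower (-0.24). The medians of other lists then became 0.31 for tuft cells (3 higher, 0 lower), 0.24 for blood endothelium (2 higher, 0 lower), 0.86 for adipocytes, 0.34 for B and plasma cells, 0.92 for pancreas acinar and 1.43 for small intestine genes, and, with a change of sign, 0.20 for proliferation, 0.02 for mesothelium and 0.19 for mast cells. The median of enteric glia became -0.05, and that of intestinal transcription factors -0.24, with 2 higher and 5 lower. Enteroendocrine genes then had 0.60 (1 higher, 0 lower) and genes of interstitial cells of Cajal 0.0002 (0 higher, 0 lower). Hox cluster A had a median of -0.62 (2 of 11 higher, 3 lower) and cluster D of -0.75 (0 of 8 higher, 3 lower), but by the ratio of the TPM values both turned positive, at 0.54 and 0.33. Log2 TPM ratios exceeded the main ratios by a median of 1.13, though not for every gene. Mitochondrial genes and their copies took 67.3% of the TPM of library 1 and 21.8% of that of library 2. With p-values adjusted over the list alone, 37 of 38 lists kept the same calls, and Hox cluster B went from 2 genes higher to 1.

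Mitochondrially encoded genes were lower together. All 13 protein genes were lower in library 2, with a median log2 ratio of -2.96 (7.78-fold lower, percentile 0), and the median stayed below 0 by the ratio of TPM values (-1.82). With the GC trend taken off, 2 of the 13 passed as lower and 0 as higher (median -0.63). The cytochrome oxidase gene mt-Co1 was at 88306 and 31070 TPM. Ribosomal protein genes went the other way: of 24, 19 were higher in library 2, 0 lower and 5 did not pass, with a median of 3.57 (11.9-fold, percentile 100). Rplp1, a stalk protein of the large ribosomal subunit, was at 23.6 and 3684 TPM, whereas Rpl23, another large-subunit protein (chosen after its values were seen), was at 763 and 843 TPM. The 12 nuclear genes of electron transport had 7 higher, 1 lower and 4 not passing (median 1.28, percentile 99.5). With the GC trend taken off 3 were higher and 1 lower (median 0.39), and with the length trend taken off the median was 0.25. Uqcrb, a complex III subunit, had 10525 and 3619 counts, and Cox4i1, a complex IV subunit, had 93 and 8341 counts.

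Over the 15711 genes with a mean expected count of at least 10, 10215 (65.0%) passed an exact binomial test with Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, 5802 of them higher in library 2 and 4413 lower. The test compares these 2 libraries, not conditions, and it has no replicate check. With total counts in place of TMM scaling every log2 ratio was 0.75 higher, and 7489 genes were higher and 1837 lower. Genes with 0 counts in library 1 led the upper end. They included Ndufa13, a complex I subunit (chromosome 8, 69894180 to 69902558; 1754 counts in library 2, at least 434-fold higher), Uqcr11, a complex III subunit (1623 counts, at least 402-fold), and Eln, elastin (1040 counts, at least 257-fold, adjusted p = 2.11e-250 by the exact binomial test). Of the 10 lowest ratios, several were pseudogenes or near-identical copies whose counts are uncertain. An example is the histone pair Hist2h3c1 and Hist2h3c2, with 839 and 33.6 counts as a sum. In all, 2459 genes were at least 10-fold higher in library 2 and 56 at least 10-fold lower. With the dispersion between the libraries as the noise (edgeR exact test, common dispersion), 0 genes passed, and 1030 had an unadjusted p under 0.05.

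Across genes, the log2CPM values of the libraries had a Pearson correlation of 0.720 and their TPM values a Spearman rho of 0.662. The genes are not independent replicates. The median chi-square of a gene was 103, against 0.455 for counting noise, so the libraries were not 1 library deposited again. Of 4542 nuclear genes with at least 10 TPM in both libraries, 1985 (43.7%) were within 1.5-fold. At a threshold of 1 TPM, 11024 genes were detected in library 1 and 14618 in library 2, with 10762 in both, 262 in library 1 alone and 3856 in library 2 alone. These numbers and the 43.7% rest on TPM over all genes, of which mitochondrial genes and their copies took 67.3% in library 1 and 21.8% in library 2. The threshold was therefore stricter for nuclear genes in library 1. The median GC content (share of G and C bases in the transcripts) was 42.0% for the 262 genes and 56.04% for the 3856 genes, against 48.2% for genes detected in both.

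The log2 ratio was higher at higher GC content (Spearman rho 0.90 across 15664 genes, which are not independent replicates). The 962 genes of 38 to 41% GC were 4.15-fold lower in library 2 at the median (log2 ratio -2.05), and 934 of them passed the test as lower. The 2512 genes of 47 to 50% GC had a median of -0.24. The 1854 genes of 56 to 59% GC were 13.8-fold higher (log2 ratio 3.78), with 1757 passing as higher. With effective length rho was -0.27, and the median log2 ratio went from 1.37 in the shortest of 5 equal groups of genes to -0.67 in the longest. Genes of 46 to 52% GC, a range chosen after seeing the data, matched more closely: their TPM values had a Spearman rho of 0.913 over 5065 genes. With the GC trend taken off, an alternative chosen after seeing the data, 3658 genes passed. The list medians were then 0.95 for general epithelium (6 of 12 higher, 2 lower) and 0.59 for colonocytes (4 of 14 higher, 0 lower). Goblet cells had 1.54 (9 of 11 higher, 0 lower) and smooth muscle 0.78 (7 of 15 higher, 1 lower). Ribosomal proteins had 1.91 (17 of 24 higher, 0 lower) and mitochondrially encoded proteins -0.63 (0 of 13 higher, 2 lower). Of the 5 red blood cell genes, 4 were still higher.

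**Figure D3:**
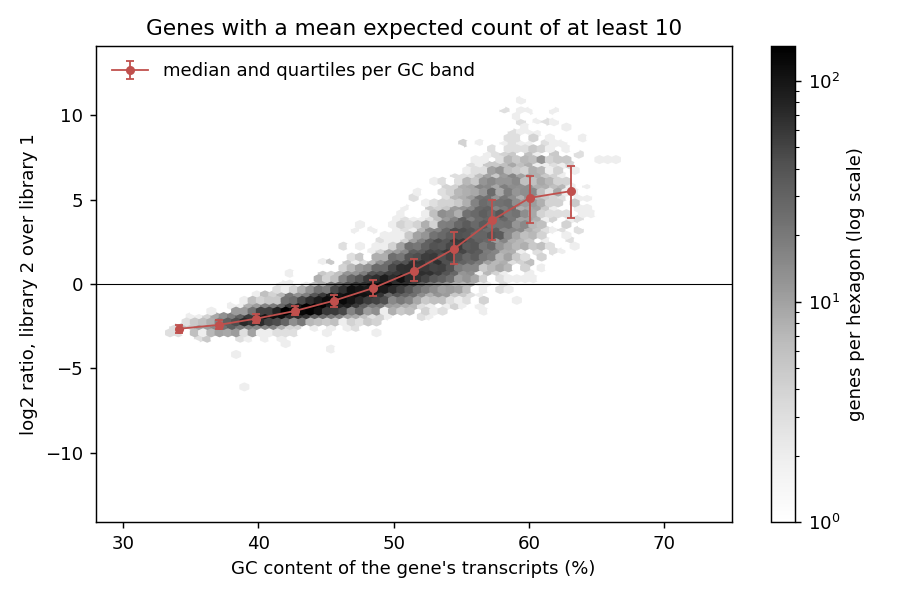
Log2 ratio of library 2 over library 1 (vertical axis) against GC content of the gene's transcripts in percent (horizontal axis) for genes with a mean expected count of at least 10, with hexagons shaded by number of genes on a log scale and red points for the median and quartiles of each GC band. Medians go from -2.66 below 35% GC to 5.51 above 62% GC.

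Among the ribosomal protein mRNAs, TPM ranged from 0.37 to 763 in library 1 (2061-fold) and from 437.5 to 3684 in library 2 (8.42-fold). Their TPM had a Spearman rho with GC of -0.65 in library 1 and 0.31 in library 2, over 24 genes that are not independent replicates. For the 12 electron transport genes the ranges were 114-fold and 4.44-fold, and rho was -0.90 and -0.06.

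**Figure D4:**
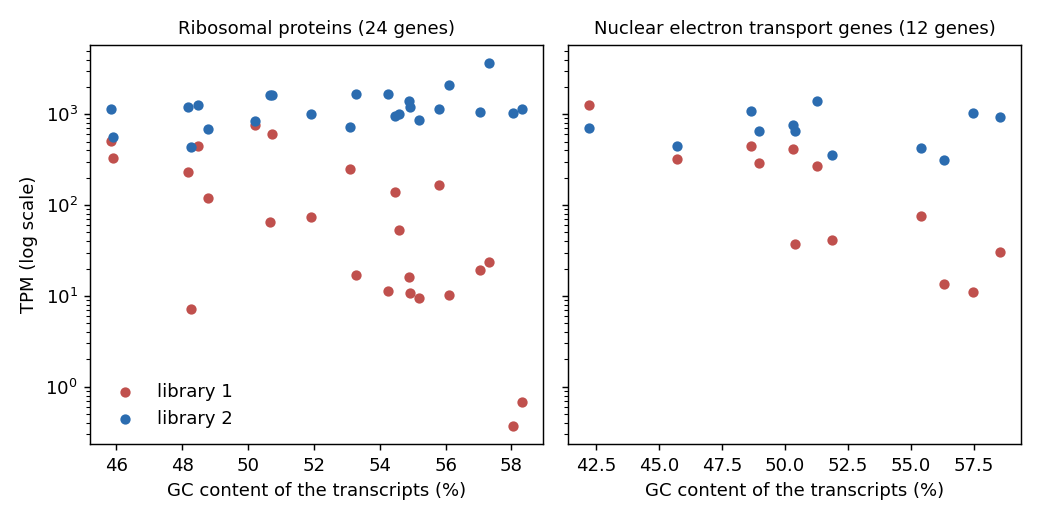
TPM (vertical axis, log scale) against GC content in percent (horizontal axis) of 24 ribosomal protein genes (left) and 12 nuclear electron transport genes (right), 1 point per gene in library 1 (red) and library 2 (blue). In library 1 the points lie lower at higher GC content, between 763 and 0.37 TPM in the left panel, and in library 2 they stay between 437.5 and 3684 TPM there.

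Transcript shares within a gene also differed between the libraries. In Tpm1 the transcript ENSMUST00000113705 took 1.64% of the gene's TPM in library 1 and 50.2% in library 2, and ENSMUST00000113695 took 51.96 and 15.4%. In Actn1, which encodes the actin cross-linker α-actinin, the leading transcript of library 1 took 99.9 and 44.4% and the other 0.0914 and 55.6%. Mylk, the myosin light chain kinase, kept 1 leading transcript at 99.3 and 99.6% (99.5 ± 0.226), and Tpm2, another tropomyosin, at 95.2 and 96.5% (95.9 ± 0.907). The variable-exon gene Cd44, an adhesion receptor, had the same leading transcript at 84.3 and 54.0%, the fibronectin gene Fn1 at 74.1 and 40.7%, and the growth factor receptor gene Fgfr2 at 64.8 and 33.6%. Itga6, a laminin receptor, had it at 60.9 and 49.1%. The 2 transcripts of Pkm, pyruvate kinase, tied at 50% in library 1, where ENSMUST00000034834 had 46.8% by posterior mean, and that transcript led in library 2 at 84.8%. The leaders differed in Cald1 (caldesmon, an actin regulator), Ctnnd1 (the cadherin partner p120) and Smtn (smoothelin), but Smtn had only 7 counts in library 1, where its leader took 73.1% of the TPM and 33.7% of the posterior mean TPM. The genes Myh11, Vcl and Myl6 each had 1 listed transcript. Of 7422 genes with several transcripts and a mean of at least 5 TPM, the leading transcript differed in 2961 (39.9%). The transcript leading in library 2 had the higher GC content in 2383 of 2863 such genes (83.2%, 95% exact interval 81.8 to 84.6%). These genes are not independent replicates, so the interval is only a description of these 2 libraries.

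Nuclear copies of mitochondrial genes took many counts. The 7 copies lie in 1 stretch of chromosome 1 (24611535 to 24616197, GRCm38, annotated as pseudogenes) and took 9.80% of the counts of library 1 and 2.84% of library 2. The pairs named next were chosen after their values were seen. Gm28439, the copy of mt-Nd4, had 122668 counts in library 1 and 22.3 in library 2, while mt-Nd4 had 513973 and 96892. Gm29216, the copy of mt-Co1, had 2719 and 65429 counts, while mt-Co1 had 2884266 and 609864. Of the 31-base words of each copy, 97.2 to 100% occurred in mitochondrial transcripts, so counts of a copy or its parent alone are uncertain.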

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

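The GC trend taken off alone, the 46 to 52% GC genes, the plain mean of GC, the transcripts of equal length and scaling without mitochondrial genes were chosen only after the main results were seen. The count of differing genes stayed within 1.5 times of 10215 under DESeq2 size factors, total counts, upper quartile scaling, both other count minimums, a 1.5-fold limit, a length trend and without mitochondrial genes (8530 to 12158). It was 3658 with the GC trend taken off, 3449 with length and GC trends, 1343 among the 5065 genes of 46 to 52% GC, where fewer genes were tested, and 0 by edgeR's exact test with the common dispersion (1030 at an unadjusted p under 0.05), since that test takes the difference between the libraries as noise. The correlation of 0.720 became 0.822 with no filter, 0.551 at a mean count of at least 100, 0.695 and 0.671 on log2 TPM with pseudocounts of 1 and 0.1, and 0.954 with the GC trend taken off. That trend was fitted to the same libraries, so a rise was built in. The rho with GC was 0.92 at a mean count of at least 100, 0.86 with the plain mean over transcripts and 0.90 with transcripts of equal length, and that with length -0.30 at a mean count of at least 100. By the median of the members the epithelial list ranked 2 in place of 3 and the colonocyte list 5 in place of 2. With TPM over nuclear protein-coding genes the sums were 4029 and 18034 for epithelium and 13338 and 22697 for colonocytes. They were 15343 and 40944 for goblet cells and 4208 and 10731 for smooth muscle. The stem cell sums, close in the main TPM, became 888 and 383. With the length trend taken off, list medians were 3.20 for epithelium, 0.30 for colonocytes, 0.98 for goblet cells, -3.96 for mitochondrially encoded and 2.03 for ribosomal proteins. With the GC trend taken off they were 0.95 for epithelium, 0.59 for colonocytes, 0.78 for smooth muscle, -0.63 for mitochondrially encoded and 1.91 for ribosomal proteins. By the TPM ratio they were 5.26, 2.17, 3.51, -1.82 and 4.45 in that order. The cause of the moves other than those of the GC trend was not tested. Of 38 lists, the median changed sign in 11 with the GC trend taken off, 10 by the TPM ratio, 4 with the length trend and 0 by DESeq2 size factors or without mitochondrial genes, and in 2 of 35 at a mean count of at least 50 (enteric glia and the female reproductive tract). With each library alone, which by design differs from the mean by less than the SD and so tests nothing, 11024 to 14618 genes were detected, and the sums were 1262 to 13587 TPM for epithelium, 4179 to 17101 for colonocytes, 4807 to 30848 for goblet cells and 1319 to 8085 for smooth muscle. No paired analysis was possible because there is 1 group. With 1 mouse, depth cannot stand in for animals. For the 130 genes with at least 100 counts in library 2 and 0 in library 1, only values at the floor of 3 counts are lower bounds.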

Other observations

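The GC trend taken off alone, the random lists matched on GC and the count without mitochondrial genes were chosen only after the main ratios were seen, and the test on the AT-rich stretch and the resampled intervals only after the spread left by the GC trend was seen. Signals that act between stroma and epithelium were measured as well. The 13 BMP and hedgehog genes summed to 136 and 199 TPM in libraries 1 and 2, or 434 and 265 TPM over nuclear protein-coding genes alone. Grem1, a BMP antagonist of crypt-base stroma, was at 45.97 and 30.2 TPM (38.1 ± 11.2, SD, n = 2), Bmp5, a BMP ligand, at 30.0 and 17.0 TPM, and Bmp2, another ligand, at 20.5 and 23.2 TPM (21.9 ± 1.95). Ihh, the epithelial hedgehog ligand, was at 0.27 and 49.9 TPM. The 12 niche Wnt and R-spondin genes summed to 39.9 and 61.95 TPM, with Wnt5a, a non-canonical ligand, at 7.10 and 6.82 TPM (6.96 ± 0.198) and Rspo3, a Wnt amplifier, at 6.65 and 5.12 TPM (5.89 ± 1.08). The sums of this list were 127 and 82.2 TPM over nuclear protein-coding genes alone. Of the BMP and hedgehog genes 5 were higher in library 2, 5 lower and 3 did not pass (median log2 ratio -0.76, which turned to 0.86 by the TPM ratio), and of 9 tested Wnt and R-spondin genes 2 were higher, 3 lower and 4 did not pass (median -0.72, or 0.44 by the TPM ratio).

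The 12 antimicrobial genes summed to 1142 and 3949 TPM, most of it Pigr, the transporter of IgA across the epithelium, at 868 and 1876 TPM, and Saa1, an acute-phase apolipoprotein, at 260 and 2011 TPM. The Saa1 and Saa2 pair is near-identical and had 2605 and 12333 counts as a sum (3.52-fold). The 10 immediate early genes, which respond to handling and stress, summed to 120 and 572 TPM, with the transcription factor genes Fos at 54.9 and 145 TPM and Jun at 17.2 and 78.3 TPM, and 7 of 10 were higher in library 2 (median 1.24). With the GC trend taken off, 0 of these were higher and 5 lower (median -0.98, percentile 0.04). The 10 histone genes summed to 233 and 609 TPM, mostly Hist1h2bc at 198 and 327 TPM. Among 15 very long transcripts, which summed to 379 and 1246 TPM, 3 were higher, 1 lower and 11 did not pass, and the cytoskeletal linker Macf1 was at 82.0 and 87.1 TPM (84.5 ± 3.63). Of the nuclear long non-coding RNAs, which summed to 1519 and 1090 TPM over 4 genes, Malat1, a speckle RNA, was at 1198 and 272 TPM and Neat1, a paraspeckle RNA, at 310.2 and 715 TPM. The multigene Sprr2a1, Sprr2a2 and Sprr2a3 set, which encodes small proline-rich barrier proteins, had 118481 and 205401 counts as a sum (1.29-fold by scaled counts). The same sum was 1843 and 23176 TPM, so its level is uncertain.

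The difference of most genes between the libraries was weighed first, and only technical explanations were tested for it. A length trend taken off left 101.6% of the number of calls, so it does not account for that number. It did move the calls, from 5802 higher and 4413 lower to 4926 higher and 5456 lower. Leaving out mitochondrial genes and their copies left 99.7%. That outcome was nearly fixed, since they are 22 of the 15711 genes and TMM scaling trims extreme ratios, so it decides nothing. With the GC trend taken off, 35.9% of the number remained, and the SD of the log2 ratio went from 2.48 to 1.26. The trend was fitted to these same ratios. Both falls therefore largely restate the rho of 0.90 with GC and are not separate support. In the same direction 2074 genes passed both times, and 633 passed in opposite directions. Within genes whose leading transcript differed, the one leading in library 2 had the higher GC content in 83.2%. The SD of log2 TPM over ribosomal protein mRNAs was 4.53 times as large in library 1 (2.89) as in library 2 (0.64). Reading this as a bias of library 1 assumes, untested here, that these mRNAs are made in near equal amounts. GC bias that lies mostly in library 1 may therefore be the main source, as a hypothesis, with the step at which it arose and the cause of the remaining calls left open.

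The nuclear copies of mitochondrial genes were weighed next. Copy and parent of mt-Nd4 and mt-Co1, pairs chosen after their values were seen, moved apart, with log2 ratios of -12.82 and -2.84 for Gm28439 and mt-Nd4, and 4.16 and -2.67 for Gm29216 and mt-Co1. The sum of each of the 7 pairs lay within 0.35 on the log2 scale of the median of the 6 mitochondrial protein genes that have no copy (-2.87). In the mt-Nd4 and mt-Co1 families the copy held at most 19.3% of the counts in either library, so the sum follows the parent and cannot decide. Those parents alone, at -2.84 and -2.67, lay closer to the median than the sums, at -3.14 and -2.53. For mt-Co2 and mt-Co3 the parents lay at -4.67 and -3.97 and the sums at -2.78 and -2.54. There the sums lay closer, as shared reads divided differently in each library would give. In the remaining families parent and sum lay about as close. Transcription of the copies themselves was not tested, and no biological explanation was tested.

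Cell type lists shifted by different amounts, which was weighed last. After the GC trend was taken off, the SD of the 20 list medians was 60.1% of its value before (95% resampling interval 36.9 to 82.4%), and 51.6% (31.2 to 75.2%) after a further trend on the GC content of the most AT-rich 350-base stretch, so GC content could be the cause of part of the spread and the share cannot be told from these lists. A different mixture of tissue layers would put epithelial lists on one side and muscle, nerve and fibroblast lists on the other. Their medians overlapped by 0.19 (gap -0.19, interval -1.94 to 0.73), although the mean of the epithelial medians was 1.04 higher (0.51 to 1.91). This explanation therefore cannot be told apart from leftover GC bias or from a length trend. With the GC trend taken off, the log2 ratio still had a Spearman rho of -0.28 with effective length. Its median then went from 0.46 in the shortest of 5 equal groups of genes to -0.20 in the longest. The share of length in the list medians after the GC trend was not tested. Red blood cell (3.19) and goblet cell genes (1.54) had the highest medians of the cell type lists after the trend. Both stood at percentile 100 of random lists matched on expression, as did ribosomal proteins (1.91). Before the trend, red blood cell and goblet cell genes stood at percentiles 99.6 and 99.9 of lists matched on GC, general epithelium at 99.4 and ribosomal proteins at 100. Hox clusters A, B and D had the lowest medians of all 38 lists after the trend (-1.21, -1.47 and -1.46, at percentiles 0.03, 0.04 and 0.03). Before it their medians were -0.62, 0.11 and -0.75. These stood at percentiles 16.6, 47.1 and 9.92 of lists matched on expression and 0.02, 0.02 and 0.03 of lists matched on GC.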
